A study of Mus musculus with 40 samples.

How the data were processed

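Long-read cDNA libraries from 4 brain regions of 10 mice were assigned to 8 groups of region and sex from the labels, with 5 libraries in each. Per the submitters' processing notes the build was mm39. The deposited annotation names Bambu as its source, a program that finds transcript models in long reads and adds them to a reference annotation. Its version, its thresholds and the reference release were not given in the sources used here. The values used were the deposited first and last positions of each transcript and exon, counted from 1, in 1 annotation made over the whole series. They carry no error, no depth and no replicate.

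The 2 deposited count tables were not used. Each has 40 columns of values under running sample names that occur in none of the labels, so that no column could be given to a library or a group. Order, size and values were not used in place of a label. In all, 80 columns of per-sample values were left out, and no total, level or comparison between regions or sexes was computed. The tests laid down before the data were examined, which compare counts between regions and between sexes, were therefore not run. The rule for named genes laid down at that time rests on those tests and was not applied. The models named were chosen after they were seen, from matched models beside genes of known function, from the fixed gene lists and from small classes. Some members of the counts given are not reported here by name. Because the annotation pools all libraries, a model may come from few reads or from 1 library.

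Added models were those without a reference identifier. Their intron chains were compared with GENCODE M39 on GRCm39, which has 481871 transcripts in 78289 genes. Of the reference transcripts in the deposited annotation, 107373 had the same versioned identifier in M39, and 107372 of these had identical exons, so that positions were compared without conversion. A chain was called the same when all intron positions were identical on the same strand; ends of the first and last exon were ignored. The classification was tested on simulated data, 5 kinds of altered M39 transcripts with 100 each, and recovered 100% of each kind. The altered transcripts had more exons than most added models, and transcripts with very short exons or introns were left out. Where the first exon was removed, a call of the same chain was also accepted. A model of an added gene was called antisense when it overlapped an annotated gene on the other strand and none on its own, same strand when it overlapped one on its own strand, and between genes otherwise.

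Intron motifs, direct repeats at intron ends, open reading frames and the genome after the 3' end were read from GRCm39. A junction was doubted when its motif was not GT-AG, GC-AG or AT-AC, or when a direct repeat of 8 bases or more spanned its ends. The genome after a model was called A-rich with 12 or more A in 20 bases. Copies elsewhere were searched with minimap2 2.31 in its spliced mode (k = 14, up to 50 secondary alignments, score ratio 0.3), requiring 90% of the length and 95% identity. The aligner placed 391 of the 392 models at their own position. Similarity of exons to the mitochondrial genome was measured with BLAST 2.17.0 at a word size of 11. As background, 2000 spliced reference transcripts with the same exon numbers as the added models were drawn at random, without regard to gene type or length.

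Shares carry 95% Wilson intervals. Matched and unmatched models were compared with two-sided Fisher's exact tests, and lengths with permutation tests of the mean log2 length (100000 permutations), with Benjamini-Hochberg adjustment over all 13 tests and a threshold of 0.05. Most of these features had been looked at before the family of tests was set. Random placement of 5' ends was done 1000 times uniformly along the chromosome, and 1000 times within 50000 bases of the own position. Models that overlap or share a gene are not independent, although the tests treat them as if they were. Alternatives were tried for the tolerance of intron positions, the M39 set, the definition of antisense and some thresholds. The thresholds varied included those for copies, direct repeats, A-rich genome and distance between starts. No alternative was tried for the length of open reading frames. The same holds for the distance between a model's 5' end and the end of an opposite-strand transcript. Work was done in Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9.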

Results

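Long-read RNA sequencing was done on 4 brain regions of adult mice, the cortex, the cerebellum, the hippocampus and the striatum. The animals were 10 C57BL/6J mice aged 20 weeks, an inbred laboratory strain, with 5 males and 5 females. Each mouse gave 1 library per region, so that 40 libraries fell into 8 groups of region and sex with 5 libraries each. The libraries were made from cDNA amplified by PCR and read on Nanopore flow cells, in which a whole cDNA molecule passes through a pore. The design asks which genes and transcripts differ between regions and between sexes. Those comparisons, and the depth of each library, were not analysed here, because the 40 columns of each deposited count table could not be given to a library from the labels. The values below describe the transcript models that the deposited annotation adds to its reference, over all libraries together and without replicates. They say nothing of the level of a model, nor of the region or sex in which it was read.

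The deposited annotation held 149874 transcript models in 57272 genes on the mouse build mm39. Of these, 149482 were reference transcripts in 56980 reference genes, and 392 were added from the reads. The deposited annotation assigned 316 of the added models to 292 added genes and 76 to 72 annotated genes. More than 1 model was listed for 21561 genes, and 10 or more for 2557. All 392 added models were spliced, 325 of them with 2 exons and 67 with 3 or more. Their exons summed to a median of 388 bases, from 99 to 1927. The longest, with 1927 exonic bases, lay on chromosome 6 from 28924227 to 28929207, antisense to Snd1, and had the intron chain of the long noncoding gene Gm68273.

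GENCODE M39, a release of the mouse annotation on the same build, was used to ask which added models had been annotated there. An added model was called matched when its whole chain of introns was that of an M39 transcript on the same strand. This held for 131 of 392 added models (33.4%, 95% Wilson interval 28.9 to 38.2%), and none of the 392 had its whole chain in the reference part of the deposited annotation. A further 8 were part of a longer M39 chain, 8 joined M39 introns in a combination that M39 does not list, and 12 had some of their introns in M39. The other 233 shared no intron with M39 (59.4%, 54.5 to 64.2%). Only 71 models matched when M39 was restricted to transcripts tagged basic, its reduced set. The intervals treat models as independent and cover counting error only.

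Matched models of added genes were nearly all long noncoding RNA. Of the 105 such models, 104 belonged to M39 genes of that type and 1 to a protein-coding gene, and they fell in 99 M39 genes. Some lay antisense to genes with known roles in the brain. On chromosome 10 from 78615335 to 78623694, a 2-exon model with the chain of Gm66870 lay antisense to Slc1a6, a glutamate transporter of Purkinje cells. On chromosome 3 from 125692841 to 125693931, the chain of Gm40145 lay antisense to Ugt8a, an enzyme of myelin lipid synthesis. These examples, like all models named here, were chosen after the models were seen.

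The 316 models of added genes differed in how often they were matched according to where they lay. Models between annotated genes were matched in 56 of 89 cases (62.9%, 52.5 to 72.2%), and models antisense to a gene in 45 of 160 (28.1%, 21.7 to 35.5%). Of these 160, 111 had an exon on an exon of the opposite strand, and the others overlapped by their span only. Models on the same strand as an annotated gene, but assigned to an added gene, were matched in 4 of 67 cases (5.97%, 2.35 to 14.4%). Among added genes, 53.3% of matched and 15.6% of unmatched models lay between genes (two-sided Fisher's exact test, adjusted p = 9.81e-11). Models on the same strand as a gene made up 3.81% of matched and 29.9% of unmatched ones (Fisher's exact test, adjusted p = 6.03e-08). Adjusted p-values are by Benjamini and Hochberg over the 13 differences tested between matched and unmatched models.

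**Figure D1:**
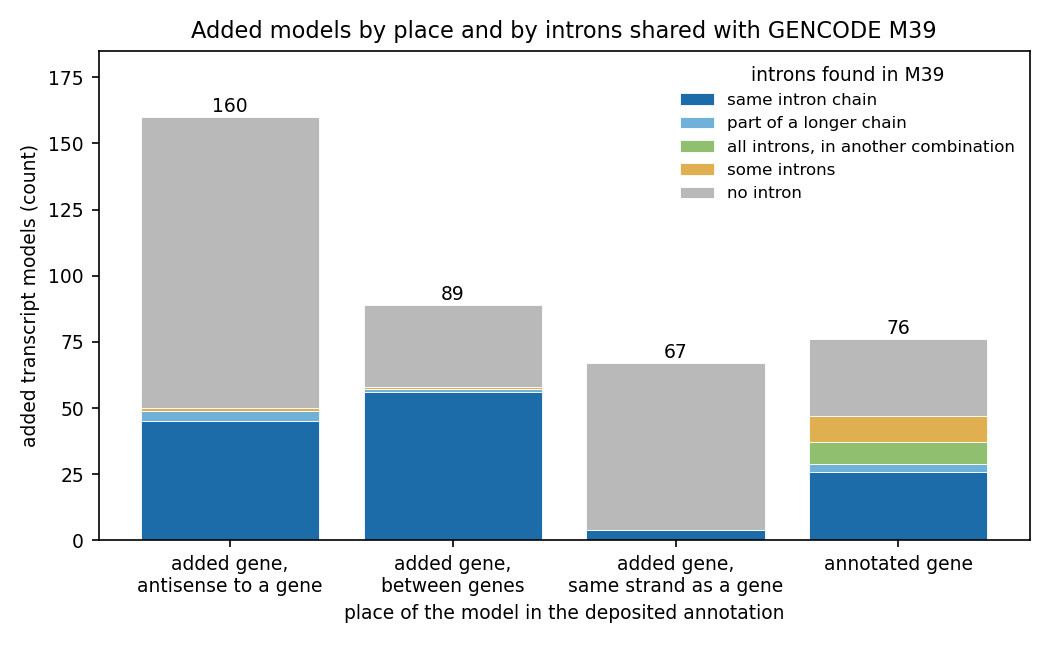
Bars count the 392 added transcript models by their place in the deposited annotation, and colours give the introns shared with GENCODE M39. Of the 89 models between genes 56 had the same intron chain in M39, against 4 of the 67 on the same strand as a gene.

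The starts of added genes were compared with those of annotated genes on the opposite strand. The 5' end lay within 1000 bases of such a start for 49 of 292 added genes (16.8%, 12.9 to 21.5%), and for 29 within 500 bases. In 1000 random placements of the same number of 5' ends along their chromosomes, the median was 6 and the highest 15. With placements within 50000 bases of the gene's own 5' end, the median was 11 and the highest 24. Added genes with a matched model had such a start in 26 of 99 cases (26.3%, 18.6 to 35.7%) and the others in 23 of 193 (11.9%, 8.07 to 17.2%; Fisher's exact test, adjusted p = 0.00397). For 16 of the 49, the opposite-strand gene was shorter than 2000 bases, mostly a pseudogene or a small RNA gene, and most of these are short enough for a model to cross whole within this distance. With longer genes only, the number was 33, made up of 26 of 99 with a matched model and 7 of 193 others (Fisher's exact test, p = 2.54e-08).

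Examples of matched models follow. On chromosome 9 from 4796293 to 4800157, a model with the chain of Gm46100 began 59 bases from the start of Gria4, a subunit of AMPA-type glutamate receptors. On chromosome 6 from 108189529 to 108189890, the chain of Gm38872 began 167 bases from the start of Itpr1, the inositol trisphosphate receptor that is abundant in Purkinje cells. The chain of Gm46054 began 10 bases from the start of Kcng4, a potassium channel subunit, and that of Gm36523 began 10 bases from the start of Oma1, a mitochondrial protease. The housekeeping genes Utp20, Ndufab1 and Coa6 also had a matched model at distances of 51, 83 and 145 bases.

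Gene lists fixed before the data were examined gave few loci, with 15 of 350 listed genes overlapped by the span of an added model on either strand or having one start beside them. Of the 16 genes of oligodendrocytes and myelin, 4 had one. Beside Ugt8a, they included Cnp, a myelin enzyme, with an unmatched antisense model on chromosome 11 from 100466632 to 100472554, whose 5' end lay 0 bases from an annotated 3' end on the opposite strand. Of the 12 Purkinje neuron genes, 3 had a model, namely Slc1a6, Itpr1 and Pcp4, a calmodulin-binding protein, whose antisense model on chromosome 16 from 96268919 to 96326993 was unmatched and also began 0 bases from such a 3' end. Of the 32 genes of synaptic adhesion and receptors, 3 had one, among them Gria4 and Dlg2, the latter with an unmatched antisense model. The intron of the Dlg2 model lay inside a 3' UTR exon of Dlg2. Its 5' end lay 67 bases from an annotated 3' end on the opposite strand. Of the 24 neurodegeneration genes, 2 had one, among them Tardbp, which shared no exon with the unmatched model that spanned it; 95.3% of that model had a near-identical copy elsewhere. The lists of cerebellar granule neurons, choroid plexus and mitochondrially encoded genes had 1 gene each, Cbln3, Calml4 and mt-Cytb, all with unmatched models, and Calml4 shared no exon with its model. The other 18 of the 25 lists had none, among them the lists for astrocytes, microglia, cortical excitatory neurons and the Y chromosome. No enrichment was tested for these lists, because the background of genes in which a model could have been added depends on read depth, which was not used here.

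Of the 76 added models assigned to annotated genes, 26 were matched (34.2%, 24.5 to 45.4%). On its strand, 67 overlapped the gene they were assigned to and 9 did not. The matched ones included models of the antisense RNAs Hopxos and Sp3os, of the small nucleolar RNA host gene Snhg7, and of Rtl8c on the X chromosome. Also matched were 2 models of Erdr1y on the Y chromosome. Of these 2, 1 had a near-identical copy elsewhere on Y, and 69.1% of the other was found on X at 100% identity. Protein-coding genes were assigned 45 of the 76, and 38 of these overlapped their gene. The 8 models that joined M39 introns in another combination were all assigned to annotated genes, namely Itgb3bp, Tmem147os, Tsg101, Mthfs, Rps12, Oaz1, Cenpx and Ntan1. With a tolerance of 10 bases at intron ends, 6 of these remained, and the models of Tsg101 and Cenpx had the whole chain of an M39 transcript. The models of Itgb3bp, Tsg101, Mthfs, Rps12 and Oaz1 had a near-identical copy elsewhere in the genome. Those of Tmem147os, Cenpx and Ntan1 had none by the same rule. Against the reference part of the deposited annotation, the 76 models held 72 introns not listed there. Both splice sites were already in use in 16 of these introns, 1 site in 26, and no site in 30.

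Splice motifs set matched and unmatched models apart. Introns began with GT and ended with AG throughout in 130 of 131 matched models (99.2%, 95.8 to 99.9%) and in 220 of 261 unmatched ones (84.3%, 79.4 to 88.2%; Fisher's exact test, adjusted p = 1.31e-06). Among 2000 annotated transcripts drawn with the same exon numbers, from any gene type, the share was 92.5% (91.2 to 93.5%). An intron beginning with AT was present in 30 unmatched and 0 matched models (Fisher's exact test, adjusted p = 8.65e-06), and in 13 of the 2000 annotated transcripts. A near-identical copy elsewhere in the genome, over at least 90% of the exonic length at 95% identity or more, was found for 10 matched (7.63%, 4.20 to 13.5%) and 78 unmatched models (29.9%, 24.7 to 35.7%; Fisher's exact test, adjusted p = 7.65e-07).

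Matched models were also longer. The geometric mean of exonic length was 483 bases in matched and 322 bases in unmatched models (two-sided permutation test, p = 2e-05, the smallest that 100000 permutations can give, adjusted p = 4.33e-05). At least 3 exons were present in 35 matched (26.7%) and 32 unmatched models (12.3%; Fisher's exact test, adjusted p = 0.00105), a difference that was lost with M39 restricted to its basic set. The genomic span did not pass the test, with geometric means of 4485 and 5042 bases (permutation test, adjusted p = 0.531). An open reading frame of at least 100 codons was present in 8.40% of matched and 8.05% of unmatched models (Fisher's exact test, adjusted p = 1), against 30.1% of the annotated transcripts (28.1 to 32.1%). These shares depend on length, since a short model cannot hold such a frame. Median exonic length was 468 bases in matched and 289 bases in unmatched models, and the annotated transcripts were not matched on length. The shares therefore do not compare coding potential. A-rich genome sequence just after the 3' end was found in 0 matched and 7 unmatched models (Fisher's exact test, adjusted p = 0.119) and in 162 of the 2000 annotated transcripts.

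**Figure D2:**
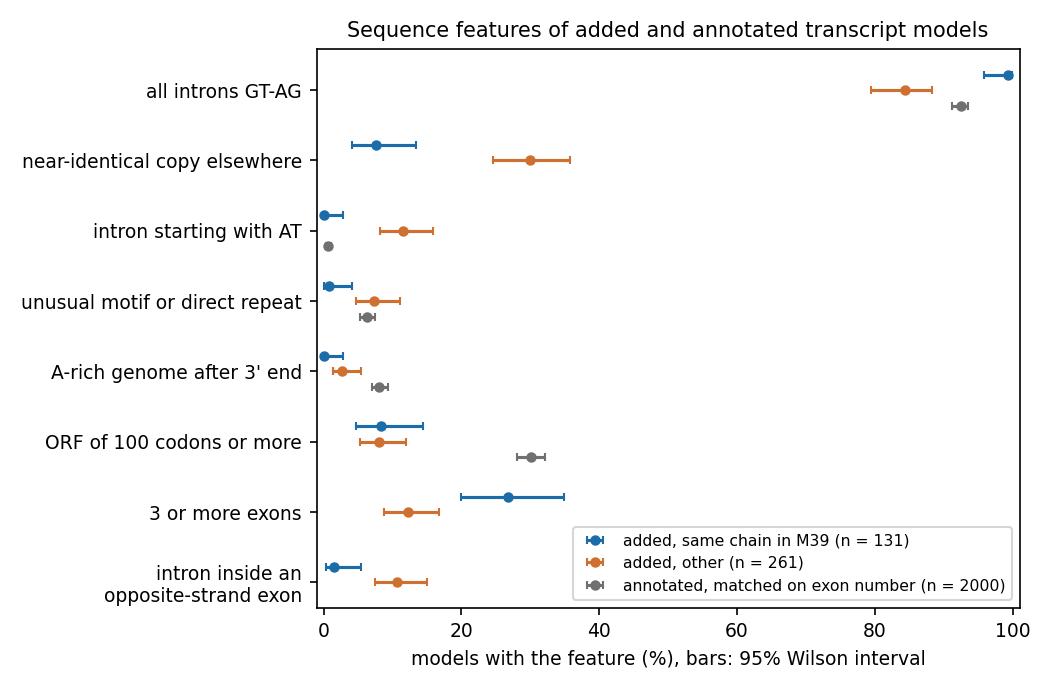
Points give the percentage of models with each feature, and bars the 95% Wilson interval, for 131 matched and 261 unmatched added models and, where computed, for 2000 annotated transcripts with the same exon numbers. All introns were GT-AG in 99.2% of matched and 84.3% of unmatched models, and a near-identical copy was found for 7.63% and 29.9%.

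Some antisense models had an intron that lay wholly inside a single exon of the opposite-strand gene. This held for 27 of 115 unmatched (23.5%, 16.7 to 32.0%) and 2 of 45 matched antisense models. Over all added models the counts were 28 of 261 unmatched and 2 of 131 matched (Fisher's exact test, adjusted p = 0.00146). The intron lay in a 3' UTR for 17 of the 27, in 16 genes. Among these were genes of neurons, such as Tubb3, a neuronal tubulin, Nptxr, a receptor for neuronal pentraxins, Cplx2 and Unc13a, which act in synaptic vesicle release, Kif1a, an axonal motor, and Lsamp, a cell adhesion protein. Cst3, the protease inhibitor cystatin C, was also among them, with 2 models. The model at Cplx2 lay on chromosome 13 from 54529655 to 54531730, with its intron from 54529978 to 54531506. The model at Kif1a lay on chromosome 1 from 92943180 to 92944671, with its intron from 92943729 to 92944479.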

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

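All alternatives here were chosen after seeing the data. Those set before the data were examined concern tests on counts between regions and sexes and were not run, since no count column could be given to a library. No paired analysis was possible because the count columns carry no animal or library that the labels name. Of 31 alternatives computed, 23 left a count within 1.5 times its value or a difference on its side of the threshold. With only M39 transcripts tagged basic, 71 models were matched, and the difference in models with 3 or more exons shrank to 6.65 percentage points and missed the threshold (Fisher's exact test, p = 0.221). The smaller set of M39 transcripts accounts for the lower count; the cause of the lost difference was not tested. Stricter or looser definitions moved 6 counts by their construction. At 98% identity 45 unmatched models had a copy elsewhere, and with direct repeats from 6 bases 29 had a doubted junction, as had 31 when AT-AC introns were doubted too. With 10 A in 20 bases, 29 ended before A-rich genome, and with 14 A, 3 did. Within 500 bases, 29 added genes began beside an opposite-strand start. Depth was not used here, so its limits on these models are unknown.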

Other observations

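Some tests were chosen only after the result was seen. They were local placement of 5' ends, restriction to long opposite-strand genes, doubting AT-AC introns, and the Fisher's exact test of ends at opposite-strand 3' ends. Other thresholds for copies, direct repeats, A-rich genome and distance between starts were also chosen then. On the sex chromosomes, 4 of 9 added models on X and 2 of 3 on Y were matched in GENCODE M39. No explanation by region or sex was tested, because no model was tied to either.

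Most added models, 261 of 392, had no M39 transcript with the same intron chain. Some technical features were weighed as the source of most of them. At the cut-offs set, each of those counted was too rare for that. Others, such as very short exons beside long introns, were not counted, so the totals below may leave out technical models. A doubted splice junction was present in 7.28% (95% Wilson interval 4.71 to 11.1%), and in 11.9% (31 models, 8.49 to 16.4%) when AT-AC introns were doubted too. The share was 0.763% in matched models (Fisher's exact test against unmatched models, adjusted p = 0.00746) and 6.30% in annotated transcripts. The annotated share is no measure of well-supported introns, because those transcripts were drawn without regard to gene type. The other features were A-rich genome after the 3' end, in 2.68% (1.31 to 5.43%, 29 models with 10 A in 20 bases), and a near-identical copy elsewhere, in 29.9% (24.7 to 35.7%, 45 models at 98% identity). Copies of under 95% identity were not counted, so the last share cannot decide on less similar sequence. For a model given the wrong strand, priming at A-rich genome would show at its 5' end instead, which was not examined. At least 1 of the 3, with AT-AC taken as sound, was present in 87 models (33.3%). With an intron inside an opposite-strand exon counted too, the number was 106 (40.6%, 34.8 to 46.7%), so they could still account for a part. A 5' end within 50 bases of an opposite-strand 3' end was not counted in these totals. It was found in 19 of the 88 unmatched antisense models without such an intron. The totals therefore set no upper limit on technical models. What the others are, including RNA that M39 does not list, stays open.

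A candidate explanation for unmatched antisense models is that reads of the opposite-strand gene's own exon, with an internal deletion, were taken as spliced. An intron inside 1 exon of the opposite strand was present in 23.5% (27 models, 16.7 to 32.0%). This argues against a deletion within 1 exon as the source of most of them. Reads of the gene's own mRNA whose gap reaches beyond 1 exon would not show it, so this share cannot decide on those. For those 27 models themselves, a 5' end within 50 bases of an annotated 3' end of an opposite-strand transcript was found in 66.7% (18 models, 47.8 to 81.4%), against 19 of the 88 other unmatched antisense models (21.6%; Fisher's exact test, p = 3.01e-05) and 1 of the 45 matched ones (2.22%). This is where reads of the gene's own mRNA, given the opposite strand, may place it, although the interval reaches below the 50% set for that test, and introns in 3' UTRs lie near such ends to begin with. Antisense RNA that begins there stays open.

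Unmatched models with 2 exons lay on a stretch of chromosome 1 that resembles the mitochondrial genome, from 24652268 to 24653052 and from 24654716 to 24655074. The exons of both were 100% identical to the mitochondrial genome over their whole length, in reverse orientation to its listed sequence. Mitochondrial RNA placed on a nuclear copy is therefore a candidate source, if it came from that reverse strand or was given the wrong strand. Sequence alone cannot tell such RNA from transcription of the nuclear copy. The first model began 2 bases from an annotated 3' end of the opposite strand, with its intron inside 1 exon of that strand. The second began 71 bases from such an end and had no such intron. Another unmatched model lay on the mitochondrial genome itself, from 14145 to 15288, opposite to mt-Cytb. Its intron, from 14430 to 14537, lay inside 1 exon of that gene.

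Chance was argued against for the 5' ends of added genes near an opposite-strand start. The observed number was 49 of 292, and none of 1000 random placements along the chromosome reached it (highest 15, one-sided permutation test by placement, p = 0.000999, the smallest they can give). Gene-dense surroundings alone are argued against as well, since the highest number among 1000 placements within 50000 bases was 24. With opposite-strand genes of at least 2000 bases the number was 33, against a highest of 12 and 18 in the respective placements. For these 33 alone, transcription in both directions from shared promoters is a hypothesis that the positions may reflect, and it was not tested.

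AT-AC introns were tested for the consensus of the minor spliceosome at their 5' end. It was found in 0 of 14 AT-AC introns (0%, upper Wilson limit 21.5%), which argues against minor spliceosome introns as most of these 14. The 9 AT-AG and 7 AT-AA introns were not tested. Of the 30 models with an intron that began with AT, 20 had a near-identical copy elsewhere.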
